A study of Mus musculus with 9 samples.

How the data were processed

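RNA was measured in 9 libraries of CD11b+ monocytes sorted from the peripheral blood of C57BL/6 mice, 8 months old, that carried Yaa. About 100000 cells went into each library per the labels, RNA was taken with Trizol, and cDNA was made with the SMART-Seq v4 Ultra Low Input kit before sequencing on an Illumina HiSeq. Each deposited file holds 1 library, with 1 value per gene symbol for 23234 symbols. The deposited values are FPKM (fragments scaled by transcript length and by mapped fragments), made by the authors for each library with no further scaling stated. The submitters' processing notes name TopHat2 2.0.8, Cufflinks 2.1.1 and the mm9 genome build, without the gene annotation or the settings. Every value column was used, so 0 columns were left out.

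No file gives read counts, so the depth of each library is unknown, and no counting interval or detection limit is given. A relative depth was estimated from the steps between the lowest FPKM values, as the size of 1 fragment in the floxed Gr-1- library divided by that in each other library. It ran from 0.71 in the library labelled null Gr-1+ replicate 1 to 2.66 in the library labelled CD19Cre Gr-1-, with the floxed library at 1. Symbols were looked up in GRCm38 annotation tables, used for names, transcript length, GC content and gene order only: 21021 were current names, 1993 were older names and 220 had no match. Small RNA genes (729 symbols) and values of 0 that Cufflinks can give when an estimate fails are a weakness of such tables. Reads from near-identical gene pairs (Ly6c1 and Ly6c2, Lyz1 and Lyz2, Fcgr2b and Fcgr3 in part, Amd1 and Amd2) cannot be assigned with certainty at the level of gene symbols.

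Libraries were grouped by the sorted subset, Gr-1+ (4 libraries) or Gr-1- (5 libraries), and by genotype. Gr-1 is the epitope shared by Ly6C and Ly6G, and the gate therefore selects on the products of Ly6c1, Ly6c2 and Itgam (CD11b), whose RNA levels still varied between libraries. For the second comparison, the genotypes were pooled by whether the label removes Fcgr2 in myeloid cells. The deleted group was null and CEBPaCre (5 libraries), and the intact group was CD19Cre and floxed (3 libraries). CD11cCre was left out because that driver acts in only part of the monocytes. These groups, the tests, the thresholds, 22 gene lists and most alternatives were set before the data were examined.

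Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(FPKM + 1), with statmod 1.5.0 for library weights and random blocks. Genes entered the fit with a mean of at least 1 FPKM over the 9 libraries and a value above 0 in at least 2 of the fitted libraries. The second condition was added after a run on simulated data, where genes with no spread were called. Genes were called at a Benjamini-Hochberg adjusted p at or under 0.05. The subset comparison had no covariate, the deletion comparison had the subset as a covariate, and a further fit added the interaction of both. Folds are ratios of the geometric means of FPKM + 1, and errors of log2 differences are standard errors.

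Gene lists with at least 5 tested members (20 of 22) were tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 20 lists. Counts adjusted over the list alone were made by adjusting the p of a list's own members. Fcgr2b was compared by an exact two-sided permutation test over all 56 assignments. Genotypes with 1 library per subset were compared as values, and the median of each list was placed among 10000 random lists of the same size drawn from 20 bins of mean expression.

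Named genes followed a rule. Fcgr2b, Fcgr1, Fcgr3 and Fcgr4 were always named. For the subsets, the rule took the 10 genes with the largest log2 difference in each direction among called genes with a mean of at least 5 FPKM in the higher subset and no overlap between subsets. For the deletion comparison it took the 10 genes with the smallest p in each direction with a mean of at least 5 FPKM in the higher group. Both comparisons added up to 4 members of each list with the smallest p, which gave 92 and 103 named genes. For pairs of single libraries it took the 5 highest and the 5 lowest log2 ratios among genes at 10 FPKM or more in either library. Predicted genes and small RNAs were left out of the ranked picks. Itgax and its neighbours, Cebpa by library and the 13 NK cell genes by library were added after their values were seen. Some results that these rules pick are not reported here.

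The numbers do not say which Gr-1+ and Gr-1- libraries came from the same mouse. Whether same-genotype libraries pair was checked by correlating, across genes, each library's deviation from its subset mean. Genes are not independent replicates, so these correlations carry no p. The correlation was 0.59 for CD19Cre, 0.19 for CEBPaCre, 0.26 for null replicate 1 and 0.16 for null replicate 2, against -0.38 to 0.25 for libraries of different genotypes. Genotype was therefore also run as a block. In that fit, CD11cCre and floxed have no Gr-1+ library and add nothing to the subset difference. It then rests on the null, CEBPaCre and CD19Cre libraries. The fits were tested on simulated data with 200 changed genes, drawn among genes of about 5 FPKM or more. The simulated libraries varied independently, also within a genotype, so the shares below need not hold for related libraries. The subset fit recovered 31.3% of genes changed 2-fold and 92.5% of those changed 4-fold. The deletion fit recovered 26.9% and 80.6%, and the interaction fit recovered 1.49% and 8.96%, rising to 63.6% at 16-fold.

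Alternatives were another pseudocount (0.1 or 5), no filter or a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, no trend, library quality weights, genotype as a replicate block, CD11cCre counted with either group, the Gr-1- libraries alone, and leaving out each library in turn. Added after the data were seen were leaving out both CD19Cre libraries, leaving out small RNA genes, genotype as a random block for the deletion comparison, and leaving out each library for the interaction. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.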

Results

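Gene expression was measured by RNA sequencing in blood monocytes of mice, 8 months old, on the Yaa background, in which the Y chromosome carries a copy of an X chromosome segment that holds Tlr7. The series asks how Gr-1+ and Gr-1- monocytes differ when Fcgr2 is removed in different cell types. Fcgr2 in the labels is listed as Fcgr2b in the files and encodes CD32, the inhibitory receptor for IgG. There were 4 Gr-1+CD11b+ libraries, labelled null (2), CEBPaCre (1) and CD19Cre (1). There were 5 Gr-1-CD11b+ libraries, 1 each labelled null, CEBPaCre, CD11cCre, CD19Cre and floxed. Null mice lack Fcgr2 in all cells per the labels, while the Cre lines remove a floxed Fcgr2 in the cells where the Cre of each label is active, and the floxed mice have no Cre. The labels do not say that libraries came from separate animals, so each p measures only the spread between libraries.

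Depth in reads was unknown, because the deposited values are FPKM. Between 9783 and 10258 genes per library had at least 1 FPKM. Both libraries labelled CD19Cre stood apart. Genes for ribosomal proteins held 2.07% and 2.39% of their summed FPKM, against 3.81% to 7.94% in the other 7 libraries. The CD19Cre Gr-1+ library listed 10140 genes at 0, the most of the 9 libraries, and the null Gr-1- library listed the fewest, 5123.

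The first comparison concerned the targeted gene. Fcgr2b averaged 137 ± 45.1 FPKM (SD, n = 5) in the libraries labelled null or CEBPaCre and 125 ± 62.5 FPKM (SD, n = 3) in those labelled CD19Cre or floxed. The log2 difference was 0.18, and the exact two-sided permutation p was 0.607 over 56 assignments, where the smallest possible p was 0.0357. This permutation did not take the subset into account, and at equal subset the log2 difference was -0.004 ± 0.32. In Gr-1+, the libraries labelled null held 200.7 and 105.9 FPKM, against 195.2 FPKM in the CD19Cre library. In Gr-1-, the library labelled null held 144.8 FPKM, against 75.0 FPKM in the floxed and 105.4 FPKM in the CD19Cre library. The CEBPaCre libraries held 148.4 FPKM in Gr-1+ and 83.05 FPKM in Gr-1-, each below the CD19Cre library of its subset. In Gr-1-, the CEBPaCre library lay above the floxed library. The CD11cCre Gr-1- library held 92.9 FPKM. The level of Fcgr2b therefore did not separate the genotypes as the labels would, and genotypes are named below only as the libraries are labelled. A value per gene cannot show whether a deleted part is missing from the transcript, since the files do not say which part was deleted, and Fcgr2b shares sequence with Fcgr3.

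Of the genes of 4 Fc gamma receptors, all detected in both subsets, 3 differed in level. Fcgr4, an activating receptor for IgG, averaged 465 ± 86.6 FPKM (SD, n = 5) in Gr-1- and 45.5 ± 23.6 FPKM (n = 4) in Gr-1+ monocytes, a 10.9-fold difference (limma adjusted p = 4.2e-05). Fcgr1, the high-affinity activating receptor, was 3.96-fold higher in Gr-1+ monocytes, at 27.5 ± 9.14 against 6.44 ± 3.18 FPKM (adjusted p = 0.00164). Fcgr3 was 2.95-fold higher in Gr-1+ monocytes, at 295 ± 160 against 94.4 ± 31.3 FPKM (adjusted p = 0.0115). For these 3 genes, no library of the lower subset reached a library of the higher one. Fcgr2b averaged 163 ± 44.5 FPKM in Gr-1+ and 100.2 ± 27.4 FPKM in Gr-1- libraries, and this difference did not pass the test (log2 difference 0.69 ± 0.26, adjusted p = 0.114). Of 19 tested genes for Fc receptors and their signalling, 3 were higher in Gr-1+, 4 were higher in Gr-1- and 12 did not pass, with 4 and 6 when adjusted over the list alone. One of the 4 was Dok1, an adaptor of inhibitory signalling (31.8 against 71.4 FPKM). The list as a group did not pass (camera adjusted p = 0.113).

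**Figure D1:**
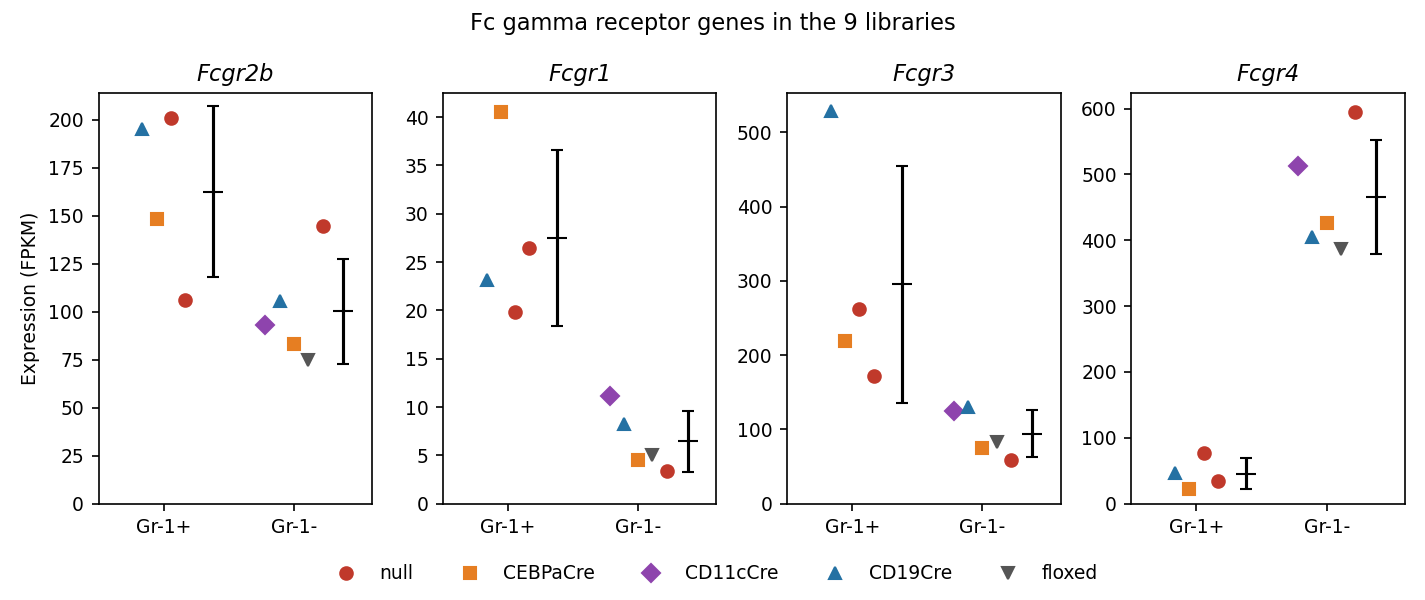
Expression in FPKM (vertical axes, linear, from 0) of 4 Fc gamma receptor genes in 4 Gr-1+ and 5 Gr-1- libraries. Each point is 1 library, with its labelled genotype given by shape and colour, and bars give the mean and SD of each subset. Fcgr4 ran from 387 to 594 FPKM in Gr-1- libraries and from 22.6 to 77.7 FPKM in Gr-1+ libraries. In Gr-1+, the libraries labelled null held the highest and the lowest Fcgr2b (200.7 and 105.9 FPKM). In Gr-1-, the library labelled null held the highest (144.8 FPKM).

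The next comparison asked how Gr-1+ monocytes differ from Gr-1- monocytes across the transcriptome. In Gr-1+, S100a8, a subunit of calprotectin, averaged 732 ± 480.5 FPKM (SD, n = 4) against 9.17 ± 2.73 FPKM (n = 5), a 64.3-fold difference, and its partner S100a9 was 46.8-fold higher. Among the other genes with the largest differences were Fn1 (fibronectin, 42.7-fold), F13a1 (coagulation factor XIII, 52.8-fold), Mmp8 (a collagenase, 66.4-fold), Lcn2 (an iron-siderophore binding protein, 61.0-fold) and Saa3 (an acute phase protein, 83.5-fold). Chi3l3, Lrg1 and Ngp completed the 10 largest. S100a8, S100a9, Lcn2 and Ngp are also in the list of neutrophil genes described below. Saa3 was uneven within Gr-1-, from 0 FPKM in the CD11cCre library to 76.8 FPKM in the CD19Cre library, and Lrg1 reached 47.5 FPKM in that CD19Cre library.

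Among the genes with the largest differences toward Gr-1-, Cd36, a scavenger receptor for lipids, averaged 128 ± 27.5 FPKM against 5.40 ± 1.93 FPKM, a 20.4-fold difference. Fabp4, a fatty acid binding protein, was 24.9-fold higher, and Pparg, a nuclear receptor of lipid metabolism, was 13.7-fold higher. The adhesion molecules Pecam1 and Itgax were 15.4-fold and 22.0-fold higher, and Cd9, Cd300e and Adamdec1 were 17.7-fold, 22.8-fold and 14.9-fold higher. Gzma (granzyme A), Ccl5 and Nkg7, which are known from cytotoxic lymphocytes, were 50.4-fold, 29.4-fold and 22.1-fold higher. Itgax in the CD11cCre library, at 300.9 FPKM, stood above the 33.8 to 65.96 FPKM of the other Gr-1- libraries.

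In all, limma called 1544 of 10436 genes, 923 higher in Gr-1+ and 621 higher in Gr-1-. With genotype as a block the count was 2712, of which 1672 were higher in Gr-1+, and 1483 genes were called both ways. The blocked difference rests on the null, CEBPaCre and CD19Cre libraries, since CD11cCre and floxed had no Gr-1+ library. No overlap between the 2 subsets was seen for 1717 genes (16.4%), where chance gives 1.59%.

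**Figure D2:**
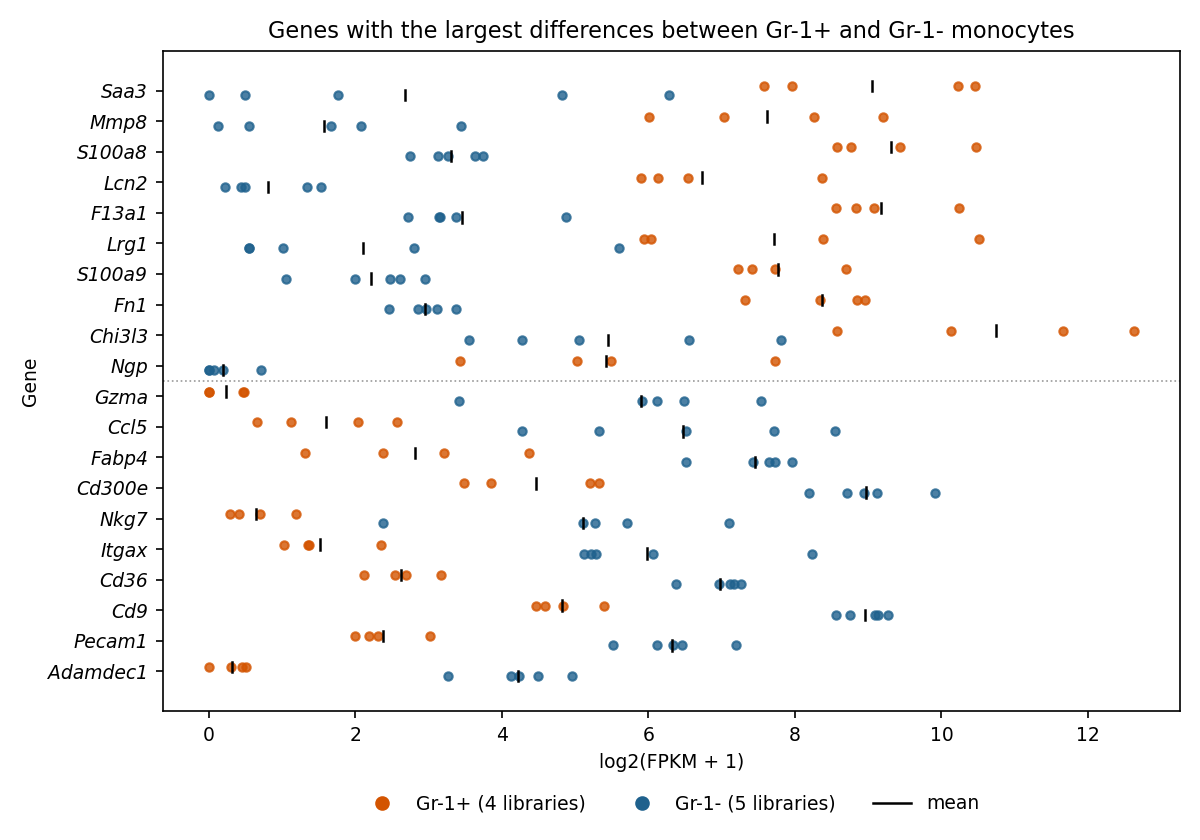
Values of log2(FPKM + 1) (horizontal axis) for the 10 genes with the largest differences in each direction. Points are single libraries, 4 Gr-1+ and 5 Gr-1-, and black ticks are means. S100a8 averaged 732 FPKM in Gr-1+ and 9.17 FPKM in Gr-1- libraries, and Cd36 averaged 5.40 and 128 FPKM.

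The genes known to mark the 2 monocyte types separated in the direction of their names. Of 21 genes of classical monocytes, 14 were higher in Gr-1+ and 7 did not pass (17 adjusted over the list alone). Ccr2, the receptor for exit from bone marrow, averaged 552 ± 115 FPKM (SD, n = 4) against 38.0 ± 17.1 FPKM (n = 5). Of 25 genes of nonclassical monocytes, 24 were higher in Gr-1- and 1 did not pass (25 adjusted over the list alone). Eno3, a muscle-type enolase, averaged 426.5 ± 130.3 FPKM in Gr-1- and 32.1 ± 6.74 FPKM in Gr-1+ libraries. The camera adjusted p was 3.3e-12 for the classical list and 6.1e-30 for the nonclassical list, and 0.019 for each with an estimated correlation. Ly6c1 and Ly6c2, 2 of the 21 classical genes, are what the Gr-1 antibody binds and so follow from the sort.

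Genes of chemokines and homing receptors went both ways, 7 higher in Gr-1+, 2 higher in Gr-1- and 10 not passing out of 19 (9 and 2 adjusted over the list alone). Ccr1, a receptor of inflammatory chemokines, was 18.3-fold higher in Gr-1+ and S1pr5, a receptor of the lipid S1P, was 10.6-fold higher in Gr-1-. Of 13 genes of cytokines and B cell survival factors, 2 were higher in Gr-1+, 5 were higher in Gr-1- and 6 did not pass (3 and 6 adjusted over the list alone). Ebi3, a subunit of IL-27 and IL-35, averaged 119 ± 41.2 FPKM in Gr-1- and 18.5 ± 5.75 FPKM in Gr-1+, and Tnf averaged 21.5 ± 4.38 and 5.64 ± 4.75 FPKM. Il18 was 3.30-fold and Tnfsf14 3.03-fold higher in Gr-1+. Of the 4 Gr-1+ libraries, null replicate 1 held the most Tnf, 12.7 FPKM against 2.83 to 3.60 FPKM. Neither list passed as a group (camera adjusted p = 0.25 and 0.271).

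Genes of lysosomes and lipid handling in macrophages included 7 higher in Gr-1+, 1 higher in Gr-1- and 12 not passing out of 20 (9 and 1 adjusted over the list alone). Trem2, a lipid-sensing receptor, was 8.78-fold and Npc2, a lysosomal cholesterol carrier, 3.37-fold higher in Gr-1+, while Nr1h3 (LXR alpha) was 3.64-fold higher in Gr-1-. Of 15 complement and efferocytosis genes, 4 were higher in Gr-1+, 1 was higher in Gr-1- and 10 did not pass (4 and 2 adjusted over the list alone). C3ar1, a receptor of complement fragment C3a, was 2.79-fold higher in Gr-1+. Of 16 genes of MHC class II presentation and costimulation, 2 were higher in Gr-1+ and 4 were higher in Gr-1- (4 and 6 adjusted over the list alone). H2-Oa and H2-Ob, subunits of the peptide-loading regulator H2-O, were 2.70-fold and 3.31-fold higher in Gr-1-, and Ifi30, a lysosomal thiol reductase, was 4.57-fold higher in Gr-1+. None of these 3 lists passed as a group (camera adjusted p = 0.207, 0.625 and 0.284), although the MHC class II list passed without the CEBPaCre Gr-1+ library (adjusted p = 0.0497, in a range of 0.0497 to 0.803 over the alternatives). The median log2 difference of the MHC class II list was 0.07 while its mean was -0.42.

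Of 22 chromosome 1 genes near Fcgr2b, 7 were higher in Gr-1+, 2 were higher in Gr-1- and 13 did not pass (8 and 4 adjusted over the list alone). The SLAM receptor Cd84 averaged 43.4 ± 0.775 against 14.9 ± 0.576 FPKM, Slamf9 was 9.58-fold higher in Gr-1-, and Pyhin1, an interferon-inducible gene, was 3.85-fold higher in Gr-1+. Of 12 genes in the X segment duplicated by Yaa, Arhgap6 alone passed (2.04-fold higher in Gr-1+, 1 adjusted over the list alone), and of 17 genes of Toll-like receptors and endosomal sensing 1 was higher in Gr-1- (1 adjusted over the list alone). These calls moved with the genotype block, where Msl3 of the Yaa segment (adjusted p = 0.0485) and Tlr1, Tlr6 and Myd88 (adjusted p = 0.0446, 0.0101 and 0.0345) also passed toward Gr-1+. Of 17 cell cycle genes, 2 were higher in Gr-1+ and 4 were higher in Gr-1- (2 and 4 adjusted over the list alone). Aurkb and Ccnb2, which act in mitosis, were 3.96-fold and 6.00-fold higher in Gr-1+. None of these 4 lists passed as a group (camera adjusted p = 0.448, 0.625, 0.328 and 0.46), and the median of the cell cycle list was -0.25 while its mean was 0.02.

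Type I interferon response genes passed as a list toward Gr-1+ (median log2 difference 1.01, camera adjusted p = 7.3e-04), with adjusted p = 0.772 with an estimated correlation. Oasl2 and Oas2, which are antiviral genes, were the 2 of 25 members called, at 4.13-fold and 3.17-fold, and 0 passed with limma when adjusted over the list alone. The mean of the list, in log2(FPKM + 1), was 5.64 in the CEBPaCre Gr-1+ library and 3.42 to 4.35 in the other Gr-1+ libraries. Without that library, the adjusted p became 0.106 for Oasl2 (range over the alternatives 0.00206 to 0.106) and 0.114 for Oas2 (0.00345 to 0.114), and each call was also lost without any 1 of several other libraries. With the genotype block, Mx2 and Xaf1 also passed toward Gr-1+ (adjusted p = 0.0166 and 0.011). Immediate early and stress genes passed as a list toward Gr-1- (median -0.54, camera adjusted p = 0.0139), with adjusted p = 0.772 with an estimated correlation. Such genes can rise with cell handling, but whether handling or the subset itself gave this difference was not tested. Of the 21 members, 2 were called, also when adjusted over the list alone, among them Hsp90aa1, which was 2.05-fold higher in Gr-1-. The call of this list was lost without the CD19Cre Gr-1+ library (adjusted p = 0.0553), without null Gr-1+ replicate 2 (0.0922), without the CD11cCre library (0.165) and with genotype as a block (0.119), in a range of 2.3e-04 to 0.772 over the alternatives.

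**Figure D3:**
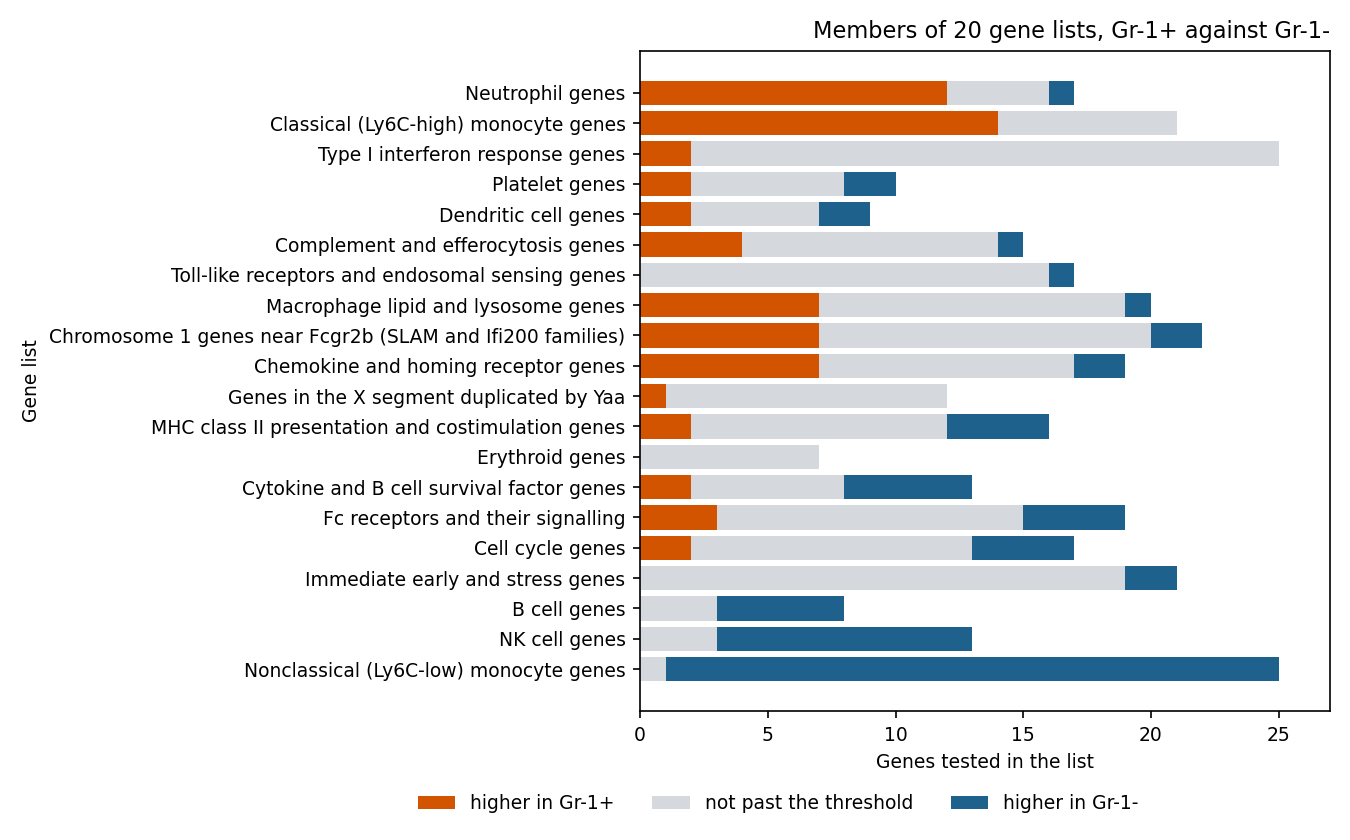
Number of tested genes (horizontal axis) in each of 20 gene lists that were higher in Gr-1+ (orange), higher in Gr-1- (blue) or did not pass the test (grey), over 4 Gr-1+ and 5 Gr-1- libraries. The nonclassical monocyte list had 24 of 25 genes higher in Gr-1-, and the classical list had 14 of 21 higher in Gr-1+.

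Markers of other blood cells also differed between the subsets. Of 17 neutrophil genes, 12 were higher in Gr-1+, 1 was higher in Gr-1- and 4 did not pass (13 and 1 adjusted over the list alone). Prtn3 (proteinase 3) averaged 36.6 ± 13.2 FPKM against 0.573 ± 0.499 FPKM, and S100a8, S100a9, Lcn2 and Ngp belong to this list. The neutrophil list passed as a group (camera adjusted p = 9.8e-11), with adjusted p = 0.0787 with an estimated correlation. The gate holds Ly6G, the neutrophil antigen that Gr-1 also binds, so a share of neutrophils in the Gr-1+ libraries stays open and untested. The list level differed within Gr-1+ from 5.40 in the CD19Cre library to 3.97 in null replicate 2.

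Of 13 NK cell genes, 10 were higher in Gr-1- and 3 did not pass (13 adjusted over the list alone). Klrd1, a subunit of an NK receptor, averaged 9.12 ± 4.63 FPKM against 0.364 ± 0.319 FPKM, and Prf1 (perforin) 13.8 ± 15.6 against 0.0572 ± 0.0427 FPKM. The camera adjusted p was 6.9e-11, with adjusted p = 0.28 with an estimated correlation. Within Gr-1-, Gzma ran from 9.67 FPKM in the library labelled null to 184 FPKM in that labelled CD11cCre. Of 8 B cell genes, 5 were higher in Gr-1- (5 adjusted over the list alone), among them Cd79a, a subunit of the B cell receptor (17.9 ± 8.63 against 0.665 ± 0.318 FPKM), and Cd72. The camera adjusted p was 1.8e-06, and 0.0363 with an estimated correlation.

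Of 9 dendritic cell genes, 2 were higher in each subset (4 and 2 adjusted over the list alone), with a median of 0.60 and a mean of -0.08. Zbtb46, a transcription factor of dendritic cells, was 2.18-fold higher in Gr-1-. The calls of Cd209a (toward Gr-1-) and Tcf4 (toward Gr-1+) were each lost under several alternatives. Their limma adjusted p ran up to 0.0964 and 0.0992. Of 10 platelet genes, 2 were higher in each subset (3 and 2 adjusted over the list alone), with F5 (coagulation factor V) 7.40-fold higher in Gr-1+ and Itgb3 4.83-fold higher in Gr-1-. The call of the platelet gene Gp9, toward Gr-1+, was also lost under several alternatives (limma adjusted p up to 0.12). With limma, 0 of 7 erythroid genes passed over all genes or over the list alone. None of these 3 lists passed as a group (camera adjusted p = 0.784, 0.328 and 0.657). The lists of T cells and of eosinophils and basophils had 2 tested genes each and were not tested as groups. Ear1, an eosinophil-associated ribonuclease, was 6.76-fold higher in Gr-1- (1 gene of its list adjusted over the list alone), and 1 T cell gene passed (1 adjusted over the list alone). Of the 20 lists tested, 7 passed, and 3 did so with an estimated correlation.

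**Figure D4:**
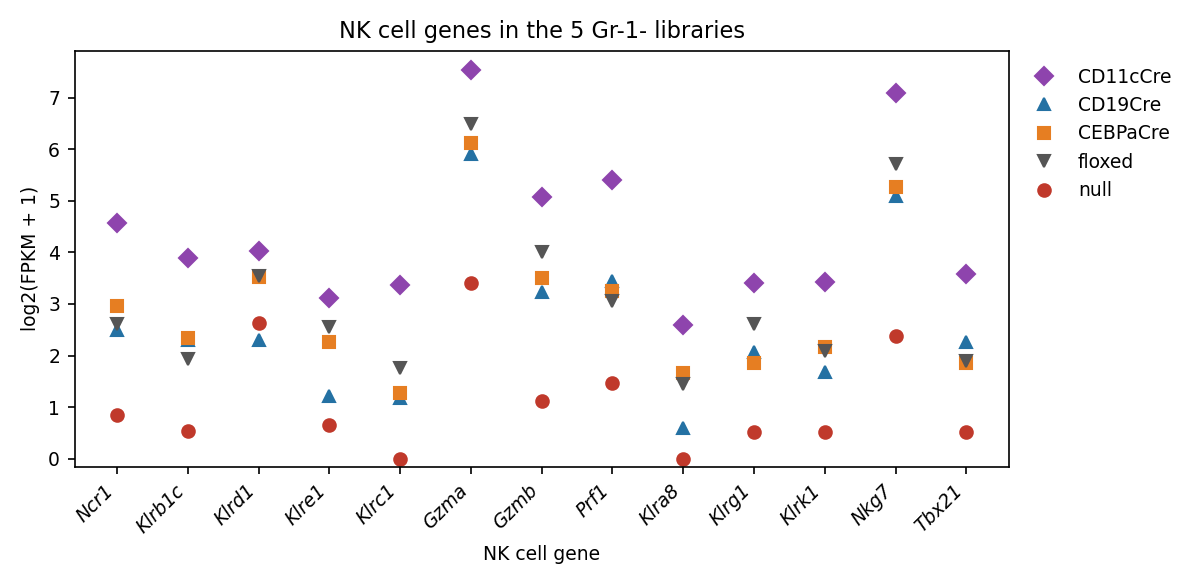
Values of log2(FPKM + 1) (vertical axis) for 13 NK cell genes in the 5 Gr-1- libraries, 1 point per library. The library labelled CD11cCre was highest and the library labelled null lowest for 12 of the 13 genes, and Gzma ran from 9.67 to 184 FPKM.

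The second main comparison asked what differed where Fcgr2 should be absent from myeloid cells, although the level of Fcgr2b did not follow the labels. Genes with the smallest p in the libraries labelled deleted included Itgam, at 171 ± 20.6 FPKM (SD, n = 5) against 65.4 ± 3.34 FPKM (n = 3), Notch2, a receptor of cell fate, at 30.3 ± 9.44 against 8.45 ± 5.84 FPKM, and Ern1, a sensor of endoplasmic reticulum stress, at 10.0 ± 1.88 against 3.38 ± 1.01 FPKM. S100a4, of the classical list, averaged 1052 ± 524 against 192.5 ± 175.5 FPKM. Dok2, an adaptor of inhibitory signalling, averaged 20.7 ± 26.1 FPKM in the libraries labelled intact and 4.24 ± 2.49 FPKM in those labelled deleted. The CD19Cre Gr-1+ library weighed most in the intact mean, at 50.6 FPKM against 5.46 to 6.53 FPKM in the deleted Gr-1+ libraries. In Gr-1-, the intact libraries held 8.90 and 2.54 FPKM, both above the 1.85 and 1.28 FPKM of the deleted ones. Fcgr3 averaged 157 ± 88.6 FPKM in the deleted and 247.5 ± 244.6 FPKM in the intact group. Its log2 difference at equal subset was -0.92 ± 0.28 (limma adjusted p = 0.306). The CD19Cre Gr-1+ library held 528.7 FPKM of Fcgr3, against 171.6 to 262.2 FPKM in the deleted Gr-1+ libraries. In Gr-1-, the intact libraries held 130.5 and 83.4 FPKM, against 75.3 and 58.9 FPKM in the deleted ones.

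With limma, 0 of 10429 genes passed, 1470 had an unadjusted p under 0.05, where chance gives 521, and the lowest adjusted p of the 103 named genes was 0.306. That excess did not last when libraries of 1 genotype were treated as related: with genotype as a random block (correlation 0.656), an alternative added later, 199 genes had an unadjusted p under 0.05 and 0 passed. The count depended on single libraries. Without the floxed library, which leaves the CD19Cre pair as the intact group, it was 2551, of which 1751 were lower in the deleted group. It was 6 without the CD19Cre Gr-1+ library and 1 without the CEBPaCre Gr-1+, the CD19Cre Gr-1- or the null Gr-1- library. It was 5 without both CD19Cre libraries, an alternative added after the data were seen. On simulated data of this design, with libraries that varied independently, 80.6% of genes changed 4-fold were called. Libraries of 1 genotype were related here (correlation 0.656), so this share does not show that 4-fold changes are absent.

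Of the 20 lists, 0 passed in this comparison. With an estimated correlation between genes, the camera adjusted p was 0.975 for each list. With the preset correlation, the lowest was 0.0782, for neutrophil genes (median log2 difference -0.61, deleted minus intact). It was 0.0861 for erythroid genes (1.10), for complement and efferocytosis genes (0.41) and for genes in the Yaa segment (0.32). For NK cell genes it was 0.0978 (-0.47). Adjusted over the list alone, limma called 3 complement and efferocytosis genes as higher in the deleted group and 1 neutrophil gene as lower. Lrp1, a receptor for dying cells, is of the complement list and averaged 69.5 ± 19.3 FPKM in the deleted group, with a log2 difference of 1.00 ± 0.25. All of these signs rest on labels that Fcgr2b did not follow. The list calls moved with the libraries: 6 lists passed without the CD19Cre Gr-1- library, 5 without the CD19Cre Gr-1+, 2 each without the CEBPaCre Gr-1+, the CEBPaCre Gr-1- or null Gr-1+ replicate 2, 1 each without null Gr-1+ replicate 1 or null Gr-1-, and 9 without both CD19Cre libraries. These counts were made with the preset correlation, under which other splits of the 8 libraries gave up to 15 lists. For interferon response genes the camera direction was up while the median was -0.02. For dendritic cell genes it was up with a median of -0.003.

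Whether deletion acted differently in the 2 subsets was tested as an interaction. The test called 9 genes, 5 with a positive and 4 with a negative term. They were Mir3061, Mir678, Mir1902, Snord95, Mir5121, Mir1894, Scarna17, Gm9846 and Rpl34-ps1, all of them small RNA genes, a predicted gene or a pseudogene, and most were listed at 0 in several libraries. No protein-coding gene of known function was among the 9. The count rose to 15 without null Gr-1+ replicate 1 and to 18 without the CEBPaCre Gr-1- library, and it was 2 without small RNA genes. The intact Gr-1+ group was 1 library, labelled CD19Cre, which was assumed to vary like the other groups, and on simulated data 8.96% of genes changed 4-fold were found.

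Single libraries of each genotype were compared as values, with no test. In Gr-1- monocytes, the library labelled null differed from the floxed library by 4-fold or more in 113 genes, that labelled CEBPaCre in 88, CD11cCre in 130 and CD19Cre in 218. The pair of null Gr-1+ libraries differed from each other in 98 genes. Over all genes the floxed library lay lower, with a median log2 difference of 0.12 for null, 0.34 for CEBPaCre, 0.35 for CD11cCre and 0.45 for CD19Cre. List medians were therefore read against random lists of like expression.

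In the null Gr-1- library, the median log2 difference from the floxed library was -1.75 for NK cell genes, -0.93 for interferon response genes and -0.96 for MHC class II genes, each below all 10000 random lists. It was also low for lists of other cells, -0.37 for B cell genes (percentile 0.09), -0.32 for dendritic cell genes (percentile 0.35) and -0.49 for platelet genes (percentile 0.01). It was 2.28 for erythroid genes and 0.64 for complement genes, above all 10000. In the null library, the gene of the chemokine Ccl5 stood at 18.4 against 209.1 FPKM in the floxed library, Nkg7 at 4.18 against 51.3 FPKM, and Igj, the J chain of antibodies, at 0.374 against 14.9 FPKM. Fkbp5, a target of glucocorticoids, stood at 42.4 against 3.97 FPKM and Rgs1 at 53.3 against 5.17 FPKM. For the CEBPaCre Gr-1- library, also labelled deleted, the median went the other way for erythroid genes (-0.48, percentile 0.01) and interferon response genes (0.49, percentile 82.9). Its percentile was less extreme than in the null library for dendritic cell genes (0.30, percentile 41.1), NK cell genes (-0.04, percentile 9.29), MHC class II genes (0.10, percentile 8.91), B cell genes (-0.16, percentile 1.28) and platelet genes (-0.13, percentile 4.54). For complement genes, the CEBPaCre median was 0.94 (percentile 100), with C1qb at 16.9 against 1.70 FPKM, the CD19Cre median 1.05 (percentile 99.7) and the CD11cCre median 0.89 (percentile 99.8). The floxed library had the lowest mean of this list among the 9 libraries, 3.64 against 4.37 to 4.81 in log2(FPKM + 1).

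The CD11cCre Gr-1- library had the highest medians against floxed for NK cell genes (1.34) and for immediate early and stress genes (1.31), both above all 10000 random lists. Cxcl2, a neutrophil-attracting chemokine, stood at 62.2 against 2.41 FPKM and Egr1, an immediate early gene, at 27.2 against 1.11 FPKM. The CD19Cre Gr-1- library held more Saa3 (76.8 against 0.404 FPKM) and Lrg1 (47.5 against 0.461 FPKM). Its immediate early and stress genes had a median of -0.32 (percentile 0.03).

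In Gr-1+ monocytes, the CEBPaCre library differed from the CD19Cre library by 4-fold or more in 209 genes and the mean of the null pair in 214. Interferon response genes had a median of 1.11 in CEBPaCre against CD19Cre, above all 10000 random lists, and cell cycle genes a median of -0.71, below all 10000. Lists of other cells and the immediate early and stress list moved in the same contrast. The medians were 0.69 for dendritic cell genes (percentile 99.3), 0.59 for platelet genes (percentile 99.05) and -0.68 for neutrophil genes (percentile 0.03). For immediate early and stress genes the median was 0.53 (percentile 99.5). S100a4 stood at 1573 against 77.9 FPKM. In the null pair, the median was 2.42 for erythroid genes, above all 10000 random lists, and -1.16 for neutrophil genes, below all 10000. Ngp stood at 17.8 against 210.4 FPKM. The null pair differed between its 2 libraries by a median of 1.65 in immediate early and stress genes, 1.02 in neutrophil genes and -0.87 in interferon response genes, at percentiles 100, 100 and 0. Nonclassical monocyte genes (percentile 100), platelet genes (percentile 0) and MHC class II genes (percentile 0) were as extreme, so 2 libraries of 1 label reached the same extremes as the genotype contrasts. Cxcl2 was 225 and 0.457 FPKM in that pair and Ccl3 133 and 4.34 FPKM. Rgs1 and Egr1, given above for single Gr-1- libraries, also differed within the pair. Rgs1 was 28.0 and 0.476 FPKM, and Egr1 was 25.2 and 0.654 FPKM. Actr3, which builds branched actin, was listed at 0 in 6 of the 9 libraries and at 294, 480.1 and 589.5 FPKM in the others, so no fold is given for it.

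Itgax, which encodes CD11c, stood at 300.9 FPKM in the CD11cCre library. Its neighbours on the chromosome stood high there too: Itgad at 35.4 against 1.79 to 6.60 FPKM in the other Gr-1- libraries, and Cox6a2 at 26.4 against 0 to 1.28 FPKM. Itgam, the neighbour on the other side, was 157 FPKM against 66.1 to 179.5 FPKM. Cebpa stood at 22.6 FPKM in the CEBPaCre Gr-1+ library, against 22.9 and 36.1 FPKM in the null pair, and at 4.49 FPKM in the CEBPaCre Gr-1- library, against 4.78 FPKM in the floxed library. In the CD19Cre libraries it was 1.64 and 1.43 FPKM.

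**Figure D5:**
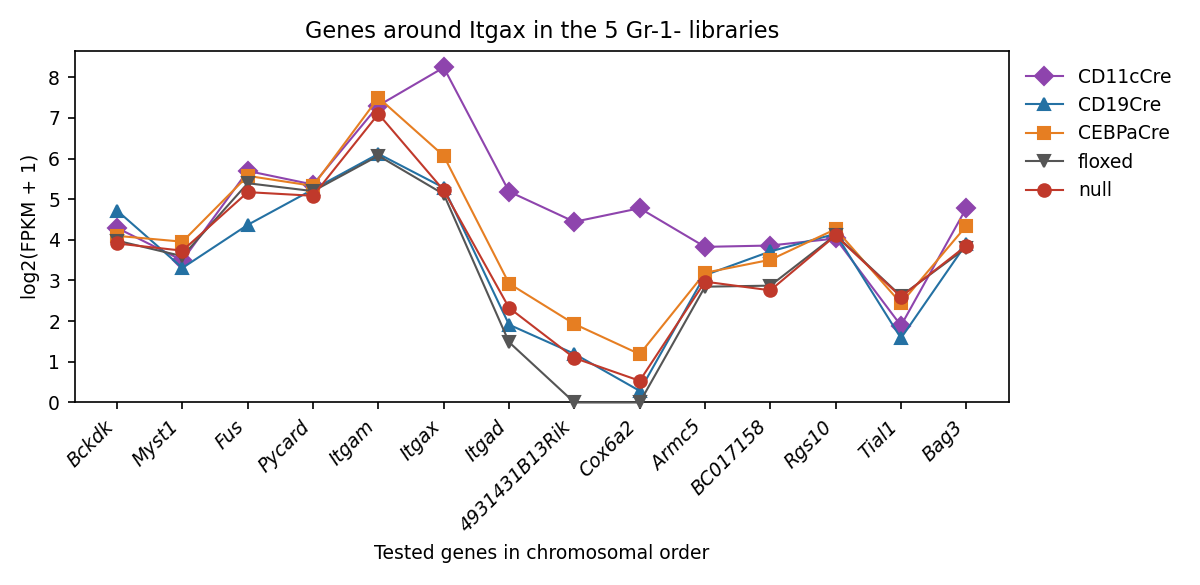
Values of log2(FPKM + 1) (vertical axis) for 14 tested genes in their order on the chromosome around Itgax (horizontal axis) in the 5 Gr-1- libraries, 1 line per library. The CD11cCre line lies above the others at Itgax, Itgad, 4931431B13Rik and Cox6a2, with Itgax at 300.9 FPKM against 33.8 to 65.96 FPKM.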

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

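The tests below were chosen after the results they concern were seen, except that on transcript length and GC content, which was planned first.

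Of 248 groups of 4 or 5 libraries, 14 held a library whose distance from its nearest neighbour took an unusually large share of the group's range, where chance marks about 5%, so their number is about what chance gives and none is singled out as a trait of its library. The CD19Cre Gr-1+ library held 3 of the 14. It had the highest Cd22, 3.21 against 0.603 to 0.796 FPKM in other Gr-1+ libraries (gap share 0.883), the highest mean of the B cell list, 2.101 against 1.101 to 1.217 in log2(FPKM + 1) (0.884), with a median log2 difference of 0.32 over its 8 genes, and the lowest Itgam, 61.7 against 170.0 to 185.7 FPKM (0.919). The CD19Cre Gr-1- library had the lowest Cebpa, 1.43 against 4.39 to 6.22 FPKM (0.732). The CEBPaCre Gr-1+ library had the highest mean of the chromosome 1 list, 5.65 against 5.22 to 5.25 (0.928), the highest Batf3, 32.2 against 17.7 to 19.6 FPKM (0.838), and the lowest Mitf, 1.89 against 3.72 to 4.13 FPKM (0.854).

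Null Gr-1+ replicate 1 had the highest mean of the nonclassical monocyte list, 5.22 against 4.53 to 4.62 (gap share 0.876), and the highest Tnf, 12.7 against 2.83 to 3.60 FPKM (0.856). Null Gr-1+ replicate 2 had the lowest sum of FPKM, 440372 against at least 544264 (0.868). The null Gr-1- library had the highest Ngp, 0.638 against at most 0.138 FPKM (0.738), and the highest Mitf, 1.39 against 0.546 to 0.668 FPKM (0.826). The CD11cCre Gr-1- library had the highest mean of the chemokine and homing receptor list, 5.05 against 4.27 to 4.37 (0.865). The floxed Gr-1- library had the lowest Tlr1, 3.95 against 7.53 to 7.86 FPKM (0.933).

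The interaction of subset and deletion, by labels that Fcgr2b did not follow, called 9 genes, but the intact Gr-1+ group was 1 library and most of the 9 were listed at or near 0 in several libraries, where an estimate can have failed. These terms are therefore given as listed, not as changes of expression. They were, in log2, -12.76 for Mir3061, -8.29 for Snord95, -6.48 for Mir678 and -6.18 for Mir1902, and 7.62 for Mir5121, 7.96 for Rpl34-ps1, 8.16 for Gm9846, 8.46 for Mir1894 and 9.83 for Scarna17. Mir3061, for example, was listed at 106 FPKM in the CD19Cre Gr-1+ library and at 0 in the other Gr-1+ libraries.

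Itgax stood high in the CD11cCre library. A run of 4 neighbours (Itgax 2.82, Itgad 3.02, 4931431B13Rik 3.39 and Cox6a2 4.28 log2 above the other Gr-1- libraries) was as high in 1 of 10077 runs of neighbours over the genome, which is itself. The run was seen before it was counted, so this count does not decide whether the CD11cCre line holds extra copies of the region, which stays open. The 9 dendritic cell genes had a median of 0.40 (SD 0.591), far under Itgax, so the list did not rise as Itgax did. Of the 9, 8 also averaged at least 1 FPKM in Gr-1+ monocytes. Their median need not follow a share of dendritic cells in the sort and does not exclude one. An effect of the CD11cCre genotype on Itgax and its neighbours by another route stays open and untested.

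Both CD19Cre libraries held the most genes at 0 of their subset and the lowest ribosomal protein shares, 2.07 and 2.39% of FPKM against 3.81 to 7.94%, and had low Rn45s, the ribosomal RNA precursor, at 43.4 and 51.4 FPKM. Lower depth should leave abundant genes in place. Yet 39.4% of 858 genes with a mean of at least 100 FPKM separated the CD19Cre pair from the deleted libraries. The share was 29.5 to 41.6% with 1 deleted library left out, which argues against depth as the whole cause. The relative depth estimated from the lowest FPKM values was 1.03 in the Gr-1+ and 2.66 in the Gr-1- library of the pair. The other libraries ran from 0.71 to 2.28. This estimate rests on the commonest ratio of low values to those of the floxed library. Only 4.5% and 5.3% of the low genes compared lay at that ratio in the pair, against 6.3% to 11.9% in the other libraries compared. It is therefore too rough to say whether the pair was shallow. With trends on transcript length and GC content taken out, 3331 genes separated the CD19Cre pair from the deleted libraries, against 2558 before, over 10277 genes with both values. The deviations of both libraries from their subsets correlated at 0.59 across genes. Genotype and an unlabelled batch cannot be told apart, because both CD19Cre libraries may share a preparation that no label records.

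NK cell genes differed between the Gr-1- libraries, and 12 of 13 were highest in the CD11cCre and lowest in the null library. Such a shared order is what a varying share of NK cells in the sorted cells could give, since the labels name only Gr-1 and CD11b and mature NK cells are known to carry CD11b. The most abundant were Gzma, at 184 FPKM in the CD11cCre and 9.67 FPKM in the null library, and Nkg7, at 135.6 and 4.18 FPKM, and 0 of the 13 genes belong to another list or reach a mean of 1 FPKM in Gr-1+ monocytes. If all other cells rose alike where monocytes were fewer, B cell genes would rise like NK cell genes. The NK median in the CD11cCre library was 2.05 (SD 0.439) and the B cell median 0.43 (SD 0.513), 1.62 apart. This argues only against an equal rise of both cell types, since more NK cells would also lower the share of monocytes. Genotype differs between all 5 libraries, so an effect of genotype on NK cells or on these genes stays open and untested.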

How the results depend on the processing

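Leaving out both CD19Cre libraries, leaving out small RNA genes, the random block, the leave-one-out fits of the interaction and the split counts for the deletion comparison were chosen after the results were seen. The 1544 genes between subsets became 2376 with library quality weights and 2712 with the genotype block, for a cause that was not tested, and stayed within 1.5 times otherwise (1063 to 2014), and within 1128 to 1578 when leaving out 1 library. Of 75 named genes called between subsets, 65 passed under every alternative run for single genes, 10 were lost under at least 1, and 0 reversed. For the lists between subsets, 3 of 7 passed with an estimated correlation, and 6 to 8 passed when leaving out 1 library.

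For deleted against intact, by labels that Fcgr2b did not follow, leaving out 1 library gave 0 to 2551 genes and 0 to 6 lists. These lists were counted with the preset correlation. With an estimated correlation and no library left out, 0 lists passed. The 2551 came without the floxed library, which leaves the CD19Cre pair as the intact group, and 56 of the 103 named genes passed there and under none of the other alternatives run for single genes. The Gr-1- libraries alone gave 12 genes, and leaving out both CD19Cre libraries gave 5 genes and 9 lists; without them, the cytokine and B cell survival factor list reversed to -0.32 (adjusted p = 0.0114, range over its alternatives 0.0114 to 0.998). The alternatives of scaling, filter, pseudocount and CD11cCre grouping gave 0 genes, as did a random block, which left 199 genes at an unadjusted p under 0.05 against 1470 in the planned fit. For the interaction, 2 genes passed without small RNA genes, and leaving out 1 library gave 7 to 18. The cause of these changes was not tested. The exact permutation p of Fcgr2b ran from 0.19 to 0.952, and 0.175 on the log2 scale became -0.13 without the floxed library.

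With a pseudocount of 0.1, the genes that differed 4-fold between single libraries rose, by construction at low values, to 188 (null against floxed), 172 (CEBPaCre against floxed), 462 (CD19Cre against floxed), 293 (CD11cCre against floxed), 419 (CEBPaCre against CD19Cre), 439 (null pair against CD19Cre) and 162 (within the null pair).

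Chance is an unlikely source of the number of subset genes. Only 1 of 100 splits of the 9 libraries, the real one, gave as many as 1544, the smallest share that 100 splits can give. The highest other gave 478, with the CD19Cre Gr-1- library moved to the Gr-1+ side. These splits do not take into account that same-genotype libraries are related. Chance cannot be excluded for the number of lists, since 40 of 100 splits gave 7 or more (highest other 10). For deletion the real counts were 0 genes and 0 lists, so all 56 splits of the 8 libraries gave as many by construction and the count decides nothing. The highest others were 1860 genes and 15 lists. The split with 1860 set both CD19Cre libraries and the CEBPaCre Gr-1- library against the rest and points to a structure of the samples, but the other splits with both CD19Cre libraries in the group of 3 gave 0 or 1 genes, and its cause was not tested. Depth in reads is unknown, so no limit from counts can be given.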

Other observations

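The values here were picked after they were seen and rest on no test.

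Hspa1a and Hspa1b, heat shock genes, stood at 232 and 208.1 FPKM in the CD11cCre and 237 and 247 FPKM in the CEBPaCre Gr-1- library, against 21.0 to 67.8 FPKM in the other Gr-1- libraries. In Gr-1+ they stood at 126 and 108 FPKM in the CEBPaCre library and at 3.02 to 13.6 FPKM in the other 3. The mean of the immediate early and stress list, in log2(FPKM + 1), ran from 5.03 in null Gr-1+ replicate 2 to 7.505 in the CD11cCre Gr-1- library.

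The mean of the MHC class II list was 4.86 in the null Gr-1- library and 5.48 to 5.92 in the other Gr-1- libraries, and the mean of the interferon response list was 2.63 there and 3.38 to 3.92 in the others. Erythroid genes had their highest mean in the null Gr-1- library, 6.96, and their lowest in the CD19Cre Gr-1+ library, 3.79. The platelet list ran from 0.982 in the null Gr-1- library to 2.34 in the CEBPaCre Gr-1+ library. Rn45s stood at 43.4 and 51.4 FPKM in the CD19Cre libraries and at 368 to 1217 FPKM in the other 7.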
